A study of Macaca mulatta with 26 samples.

How the data were processed

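The series holds RNA sequencing of the pineal gland and the retina of rhesus macaques collected around the 24-hour cycle. Per the labels, 12 animals were kept on 12 h of light and 12 h of dark, with lights on at 0600, and tissue was taken in windows around dawn (0500 to 0700), mid-day (1100 to 1300), dusk (1700 to 1900) and midnight (2300 to 0100). There were 3 libraries per tissue and time, 12 of pineal gland and 12 of retina, and 2 libraries of a control pool mixed from 16 tissues, 1 from mid-day and 1 from midnight. Libraries were made from total RNA.

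The authors deposited a table of FPKM values (fragments scaled to gene length and to the mapped total) for 50308 genes in the 26 libraries. They also deposited tables of their own comparisons. Per the file headers these give a mean normalised count (a signal on the scale of counts), a log2 fold change with its standard error, a test score, and p-values before and after adjustment. Per the submitters' processing notes the tools were FastQC, STAR 2.3.0e, Subread, featureCounts and DESeq2 with the human build hg19. The annotation, the filters and the strand setting were not given in the sources used here. Macaque reads were thus assigned to human gene models, so reads that differ from the human sequence, or that fall in near-identical copies, overlapping genes or antisense genes, may be divided between them or lost. This applies to pseudogenes such as MFAP1P1 and small RNA copies such as RNU6-518P. Of the 50308 names, 16438 (32.7%) were found in the RefSeq gene table of the macaque assembly T2T-MMU8v2.0, which was used for names alone. No reference genome was used here, so no positions are given.

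FPKM values are not counts, so the main tests used limma on log2(FPKM + 0.5) and not a count model. Fold changes are on that scale, which understates the change of genes with low values. Whole reads per gene were recovered from the steps of the FPKM values for 42804 of 42804 genes above 0, each within 0.0001 of a whole number. For a gene above 0 in a single library the steps do not fix the read number. The recovered reads gave the depth: 11.7 to 16.1 M reads assigned to genes in pineal libraries, 16.9 to 21.4 M in retina libraries, and 16.2 and 23.0 M in the control pools. In the time-of-day comparisons, 99.8% to 99.9% of genes came within 0.01 log2 units of the mean counts in the authors' deposited tables. Retina libraries were deeper than pineal libraries, which by itself lowers the counting error of low genes. Their spread between libraries was not compared between the tissues.

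Genes with an FPKM of at least 1 in at least 3 of the fitted libraries were tested. A gene present in the 2 control pools alone cannot pass that filter. Each tissue was fitted with its 12 libraries and 4 times, with empirical Bayes moderation along a mean-variance trend in limma 3.58.1 under R 4.3.3. Calls had a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. All tests were two-sided. There were 19 comparisons: midnight against mid-day, the 5 other pairs of times and a moderated F test over the 4 times in each tissue, the difference between tissues in the midnight-against-mid-day change and in the whole 4-time profile, pineal gland against retina, and each tissue against the control pools. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads, summaries and plots. The p-values measure the spread between these libraries, and per the labels the 3 of a tissue and time came from different animals.

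The groups, tests, filter, gene lists and rule for named genes were fixed before the data were examined. The 27 gene lists had 442 memberships, of which 436 were in the table: core clock, melatonin synthesis, adrenergic and cyclic AMP signalling, immediate early response, rod phototransduction, cone phototransduction, photoreceptor genes of rods and cones, pineal and retinal transcription factors, other retinal neurons, Muller glia, retinal pigment epithelium, oligodendrocytes, astrocytes, choroid plexus, blood, microglia and macrophages, connective tissue and vessels, tissues of the control pool, heat shock, endoplasmic reticulum stress, glucocorticoid response, cholesterol synthesis, interferon response, retinal dopamine and melatonin signalling, oxidative phosphorylation, cytosolic ribosome, and sex-linked genes. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, then with an estimated correlation, and with fry.

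For midnight against mid-day, the named genes were the 12 largest changes in each direction among called genes with a mean FPKM of at least 2, no overlap between the libraries of the groups and a name that is not a clone or numbered locus. For the F test they were the 12 smallest p-values with the same level and name rule, for the interactions the 10 smallest p-values, and for tissues and control pools the 12 largest changes in each direction with a mean of at least 5. In every comparison the core clock and melatonin lists were added in full, with up to 4 members of each other list. The midnight-against-mid-day rule was applied to the other pairs of times after their counts were seen.

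On simulated data, limma recovered 61 of 100 genes changed 2-fold and 81 of 100 changed 4-fold for the pineal midnight-against-mid-day comparison, with 11 false calls over 19149 genes. For the same comparison in the retina it recovered 58 and 75 of 100, with 9 false calls over 21882 genes. A list moved on purpose passed all 3 list tests, and 0 of 20 lists left in place was called by camera or fry. The simulated genes varied independently, so this does not cover lists whose genes vary together.

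Alternatives fixed in advance were other pseudocounts, no filter or a stricter filter, a median-ratio rescaling, quantile normalisation, other moderation settings, a minimum fold change, the replicate number as a block, fits on fewer times, and leaving out each library. Added after seeing the data were voom on the recovered reads with and without library quality weights, an XIST and EIF1AY indicator for the sex of the animals, and fits that left out, marked or matched the 2 retina libraries with over 40% of genes at 0. The authors' deposited table of pineal gland against control was not used as a pineal result, since all 50308 of its entries were identical to those of their retina table. Results for some single genes are not reported here.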

Results

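RNA was sequenced from the pineal gland, the brain's source of circulating melatonin, and from the retina of rhesus macaques at dawn, mid-day, dusk and midnight. Per the labels the animals were 3 to 33 years old, of both sexes, and were collected over 11 years. Each tissue had 3 libraries per time, and 2 pools of 16 other tissues, 1 from mid-day and 1 from midnight, gave the background level of each gene. The design asks which genes mark the pineal gland and the retina against the rest of the body and against each other, which genes differ between times of day, and whether the times differ in the same way in both tissues. Pineal libraries held 11.7 to 16.1 M reads assigned to genes, retina libraries 16.9 to 21.4 M and control pools 16.2 and 23.0 M. The 24 pairs of libraries from the same tissue and time all differed by more than sampling noise, with a chi-square per gene of 10.1 to 46.9. XIST, transcribed from the inactive X chromosome, and EIF1AY, on the Y chromosome, divided the tissue libraries cleanly, with XIST high in 7 of 12 pineal and 5 of 12 retina libraries. By time, XIST was high in 1 dawn, 3 mid-day, 2 dusk and 1 midnight library of the pineal gland, and in 0, 1, 3 and 1 of the retina. Those counts need at least 16 animals, while the labels give 12, and pineal and retina libraries with the same number fell on different sides in 6 of 12 pairs. In the retina, dawn 2 and mid-day 1 had 44.8% and 45.7% of genes at 0, against 33.5% to 35.2% in the other 10 libraries and 43.1% to 47.9% in the pineal libraries.

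Between mid-day and midnight, 8 of 19110 pineal genes passed the adjusted threshold by limma, 3 higher and 5 lower at midnight. At an unadjusted p under 0.05 there were 2025 genes, where 955.5 were due by chance, so the number of calls does not give the number of changed genes. TGFBR3, a co-receptor for transforming growth factor beta, was at 24.01 ± 1.24 FPKM at mid-day and 60.8 ± 1.25 at midnight (SD, n = 3), a log2 change of 1.32 ± 0.14 (SE, limma adjusted p = 0.0117), with all 3 midnight libraries above all 3 mid-day libraries. SMCO4, a small membrane protein, rose from 2.61 ± 0.352 to 6.51 ± 0.928 FPKM (log2 1.17, adjusted p = 0.0283). In the other direction, ADAMTS16, a secreted metalloprotease, was at 6.67 ± 1.79 FPKM at mid-day and between 0.0717 and 0.101 at the 3 other times, and its log2 change at midnight was -3.62 ± 0.26 (adjusted p = 0.000709). RFFL, a ubiquitin ligase, went from 13.9 ± 4.02 FPKM at mid-day to 3.63 ± 0.273 at midnight (log2 -1.77, adjusted p = 0.0176). The U6 small RNA copy RNU6-518P (log2 -1.64, adjusted p = 0.0176) and the pseudogene MFAP1P1 (log2 -1.23, adjusted p = 0.0283) were also lower. The other calls, named after their values were seen, were AP001925.1, which was listed at 0 in the pineal libraries of every time but mid-day, and RP11-137H2.6, which was higher at midnight (log2 1.23). XIST was high in 3 of 3 mid-day and 1 of 3 midnight libraries. With the XIST and EIF1AY indicator in the model 2 of the 8 were left, both lower, ADAMTS16 among them.

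None of the enzymes of melatonin synthesis passed between mid-day and midnight. AANAT, which acetylates serotonin and gives the hormone its nightly rhythm, was at 59.8 ± 1.67 FPKM at mid-day and 48.4 ± 4.38 at midnight (SD, n = 3; log2 -0.31 ± 0.13, limma adjusted p = 0.432). ASMT, the last enzyme of the pathway, was at 120.3 ± 40.3 and 168.3 ± 25.4 FPKM (adjusted p = 0.426), and TPH1, the first, at 611.5 ± 178.4 and 600.9 ± 126.4 (adjusted p = 0.992). The limma counts of the 11 genes of the melatonin list were 0 over all genes, and 0 of the 25 measured clock genes did in either form of adjustment, including PER1 (log2 0.35, adjusted p = 0.639), PER2 (0.05, 0.936) and ARNTL (-0.40, 0.302). Among lists, immediate early response genes had a median log2 change of 0.69 (camera adjusted p = 0.000224, but adjusted p = 0.505 with an estimated correlation). Interferon response (0.00142; adjusted p = 0.418 with an estimated correlation), microglia and macrophages (0.00471; adjusted p = 0.505 with an estimated correlation) and cytosolic ribosome (0.0434; adjusted p = 0.712 with an estimated correlation) behaved alike, and each had 0 called members. The number of called genes rested on single libraries: it was 252 without mid-day 3, 2 without midnight 3, and 0 without mid-day 1 or mid-day 2, where 1442 and 1548 genes had an unadjusted p under 0.05. ADAMTS16 passed without each of the 3 midnight libraries. Without any 1 of the 3 mid-day libraries it fell below the expression filter, which asks for 3 libraries, and was not tested. TGFBR3 lost its call without midnight 3 (limma adjusted p = 0.0795), mid-day 1 (0.124) or mid-day 2 (0.102). RNU6-518P lost it without the same libraries (0.0843, 0.127 and 0.102), RFFL also without midnight 2 (0.0599), and SMCO4 also without midnight 1 (0.0577). MFAP1P1 lost it without midnight 2 (0.0846), midnight 3 (0.140), mid-day 1 (0.127) or mid-day 2 (0.215).

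With all pineal libraries in the fit, the pair of times with the most called genes was dawn and dusk. This order rested on a single library. Without dusk 2 there were 0 calls between dawn and dusk, while calls from mid-day to dusk remained. Without mid-day 3 there were 252 calls between mid-day and midnight, but dawn and dusk were not compared without that library. DRD4, CCKBR and TYRO3 were among the genes lower at dusk and AIPL1, GUCA1A and PRCD among those higher. DRD4, the D4 dopamine receptor, was at 53.0 ± 11.4 FPKM at dawn and 4.73 ± 0.746 at dusk (SD, n = 3), a log2 change of -3.34 ± 0.30 (SE, limma adjusted p = 0.00768). CCKBR, the gastrin and cholecystokinin B receptor, went from 44.5 ± 11.4 to 3.28 ± 0.851 FPKM (log2 -3.57, adjusted p = 0.0122), and TYRO3, a receptor tyrosine kinase, from 26.8 ± 11.5 to 3.48 ± 0.49 (log2 -2.71, adjusted p = 0.0142). The D2 dopamine receptor DRD2 (log2 -1.98), the serotonin receptor HTR1E (-2.42), the T-type calcium channel CACNA1G (-2.65), the amino acid transporter SLC6A17 (-4.15) and RNF152, a ubiquitin ligase (-2.77), were lower at dusk too. In the other direction, AIPL1, a chaperone of the phosphodiesterase of photoreceptors, rose from 11.2 ± 2.59 to 34.0 ± 2.0 FPKM (log2 1.59, adjusted p = 0.0142). GUCA1A, an activator of retinal guanylate cyclase, went from 48.6 ± 11.2 to 200.9 ± 49.1 (log2 2.03, adjusted p = 0.0233), and PRCD, a protein of photoreceptor discs, from 2.21 ± 0.118 to 6.70 ± 1.02 (log2 1.40, adjusted p = 0.0204). LRTM1, a membrane protein with leucine-rich repeats, was higher by log2 3.53. PDE6B, the rod phosphodiesterase beta subunit, was lower at dusk (log2 -1.23, adjusted p = 0.0401).

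In all, 112 of 19110 genes differed between dusk and dawn, 52 higher and 60 lower at dusk, with 3249 at an unadjusted p under 0.05. The list of retinal dopamine and melatonin signalling, with 5 measured members, had 3 lower at dusk (DRD4, DRD2 and DDC) and 3 adjusted over the list alone (camera adjusted p = 9.18e-06, adjusted p = 0.0215 with an estimated correlation). DDC, the decarboxylase that makes serotonin and dopamine, was at 140.6 ± 35.3 FPKM at dawn and 46.8 ± 9.57 at dusk (SD, n = 3; log2 -1.57, limma adjusted p = 0.0343) and was the 1 gene of melatonin synthesis called. Of 17 measured photoreceptor genes of rods and cones, 3 were higher and 0 lower, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.09 with an estimated correlation). The adrenergic and cyclic AMP list had 1 of 21 genes lower, DRD4, and 10 lower with 1 higher adjusted over the list alone (camera adjusted p = 0.00926, adjusted p = 0.09 with an estimated correlation). Melatonin synthesis (0.0186; adjusted p = 0.321 with an estimated correlation), immediate early response (0.0186; adjusted p = 0.754 with an estimated correlation), endoplasmic reticulum stress (0.0186; adjusted p = 0.527 with an estimated correlation) and cholesterol synthesis (0.0293; adjusted p = 0.754 with an estimated correlation) passed with the preset correlation alone. XBP1, a transcription factor of the unfolded protein response (log2 -1.13), and RPL14 of the ribosome (log2 -1.30) were the called members of their lists. MBP, a myelin gene of oligodendrocytes, was at 37.8 ± 39.0 FPKM at dawn, 15.0 ± 15.6 at mid-day, 20.02 ± 7.46 at dusk and 10.5 ± 2.75 at midnight. The number of called genes was 108 with voom, 24 higher and 84 lower, 79 of them shared with limma. With quality weights voom called 484, 135 higher and 349 lower. The limma count was 0 without dusk 2 (2289 genes at an unadjusted p under 0.05), 3 without dusk 1, 61 without dusk 3, 9 without dawn 1, 3 without dawn 3, and 31 with the XIST and EIF1AY indicator in the model. DRD4 passed without each library except dusk 2 (limma adjusted p = 0.079), TYRO3 and AIPL1 without each except dusk 2 (both 0.079) and dusk 1 (both 0.0528), and CCKBR without each except those and dawn 3 (0.0528). The other named genes were less steady. GUCA1A lost its call without dusk 1 (limma adjusted p = 0.0959), dusk 2 (0.119), dawn 1 (0.0573) or dawn 3 (0.0983). PRCD (up to 0.109), DDC (up to 0.135), CACNA1G (up to 0.122) and SLC6A17 (up to 0.109) lost it without the same 4, and LRTM1 without the same except dawn 1 (up to 0.0983). DRD2 lost it without any 1 of the 6 libraries (0.0526 to 0.135). HTR1E (up to 0.141), RNF152 (up to 0.122) and XBP1 (up to 0.141) lost it without any but dawn 2, and PDE6B (up to 0.151) and RPL14 (up to 0.135) without any but dusk 3.

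Fewer genes passed in the other pairs of pineal times, and the 3 comparisons with dusk used the same 3 dusk libraries. From dusk to midnight, DRD4 rose by log2 3.05 (limma adjusted p = 0.00922) to 43.3 ± 9.1 FPKM (SD, n = 3), CCKBR by 3.12 (0.0221), TYRO3 by 2.21 (0.0475) and TGFBR3 by 1.44 (0.00922). RNU6-518P (log2 -1.63), RFFL (-1.47), the kinetochore gene CENPT (-1.65) and the membrane protein TMEM54 (-1.27) were lower at midnight, among 11 genes called, 6 higher and 5 lower. TYRO3, RFFL, CENPT and TMEM54 each lost the call without any 1 of the 6 libraries (limma adjusted p up to 0.204), and RNU6-518P without any but midnight 2 (up to 0.165). CCKBR lost it without midnight 3 (0.112), dusk 1 (0.109) or dusk 2 (0.165), and DRD4 (0.0908) and TGFBR3 (0.0659) without dusk 2. From mid-day to dusk 4 genes passed, with 737 at an unadjusted limma p under 0.05, where 955.5 were due by chance. The 4 were ADAMTS16 (log2 -3.55), DRD4 (-2.59, adjusted p = 0.0222), AP001925.1, listed at 0 at dusk, and RP11-137H2.6 (1.29). DRD4 lost this call without any of the 3 dusk libraries (0.145, 0.154 and 0.0758) or mid-day 2 (0.286). From dawn to mid-day 6 genes passed: ADAMTS16 (log2 3.57) and AIPL1 (1.53, adjusted p = 0.0203) were higher, as were the microRNA gene MIR4664 and AP001925.1, both listed at 0 at dawn, and C4orf26 (-3.40) and RP11-137H2.6 (-1.16) were lower. AIPL1 lost the call without mid-day 1 (limma adjusted p = 0.129), mid-day 2 (0.176) or dawn 2 (0.0629), and MIR4664 without mid-day 1 (0.113) or mid-day 2 (0.0813). Those called genes outside the naming rule were named after their values were seen. Between midnight and dawn limma called 0 genes, with 1819 at an unadjusted p under 0.05, and voom called 0 with 1791. The dopamine and melatonin signalling list passed in the 2 other comparisons with dusk, which are not independent of each other, from mid-day to dusk (camera adjusted p = 1.66e-07, adjusted p = 0.00915 with an estimated correlation) and from dusk to midnight (1.82e-06, adjusted p = 0.0174 with an estimated correlation). Oligodendrocyte markers had a median log2 change of -1.20 from dawn to mid-day (camera adjusted p = 0.029, adjusted p = 0.774 with an estimated correlation).

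Across all 4 times together, 20 pineal genes passed the limma F test, led by ADAMTS16 (adjusted p = 0.00113), TGFBR3 and DRD4 (both 0.00683), CCKBR (0.0119), AIPL1 and MIR4664 (both 0.0191) and TYRO3 (0.0238), while AANAT did not (0.38). LGALS3BP, a secreted glycoprotein, followed a later course, at 9.13 ± 1.88 FPKM at dawn, 7.85 ± 0.716 at mid-day, 17.4 ± 2.24 at dusk and 16.8 ± 1.92 at midnight (SD, n = 3; adjusted p = 0.0373). voom called 16 genes, 14 of them shared. The F test count was 378 without mid-day 3, 13 without dawn 1 or midnight 2, 9 without mid-day 2, 7 without dawn 3 or dusk 1, 6 without dusk 2, and 4 without mid-day 1 or midnight 3. Single libraries also moved the counts of the other pairs. From dusk to midnight the 11 calls became 6 without midnight 1, 4 without midnight 3, 3 without dusk 1, 7 without dusk 3 and 0 without dusk 2 (1751 at an unadjusted p under 0.05), and voom called 1. From mid-day to dusk the 4 calls became 2 without dusk 1, dusk 2 or mid-day 3, 1 without mid-day 1 and 0 without mid-day 2 (1086), and voom called 1. From dawn to mid-day the 6 calls became 182 without mid-day 3, 10 without dawn 1 and 0 without mid-day 1 (2319) or mid-day 2 (2074), and voom called 3. From midnight to dawn, 1 gene passed without dawn 1. TGFBR3 kept its F test call without each of the 12 libraries, ADAMTS16 without each of the 9 outside mid-day, and DRD4 without each but dusk 2 (limma adjusted p = 0.0528). CCKBR lost it without dusk 1, dusk 2 or midnight 3 (adjusted p up to 0.0548), AIPL1 without these or mid-day 1 (up to 0.0651), and TYRO3 without these, mid-day 1 or midnight 2 (up to 0.106). MIR4664 lost it without dawn 1, dawn 3, mid-day 1 or midnight 3 (up to 0.0632), and LGALS3BP without each of 9 libraries, keeping it without dawn 2, mid-day 3 or midnight 1 (up to 0.096). With the XIST and EIF1AY indicator, 6 genes passed the F test, 2 the step from dawn to mid-day and 3 that from dusk to midnight.

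**Figure D1:**
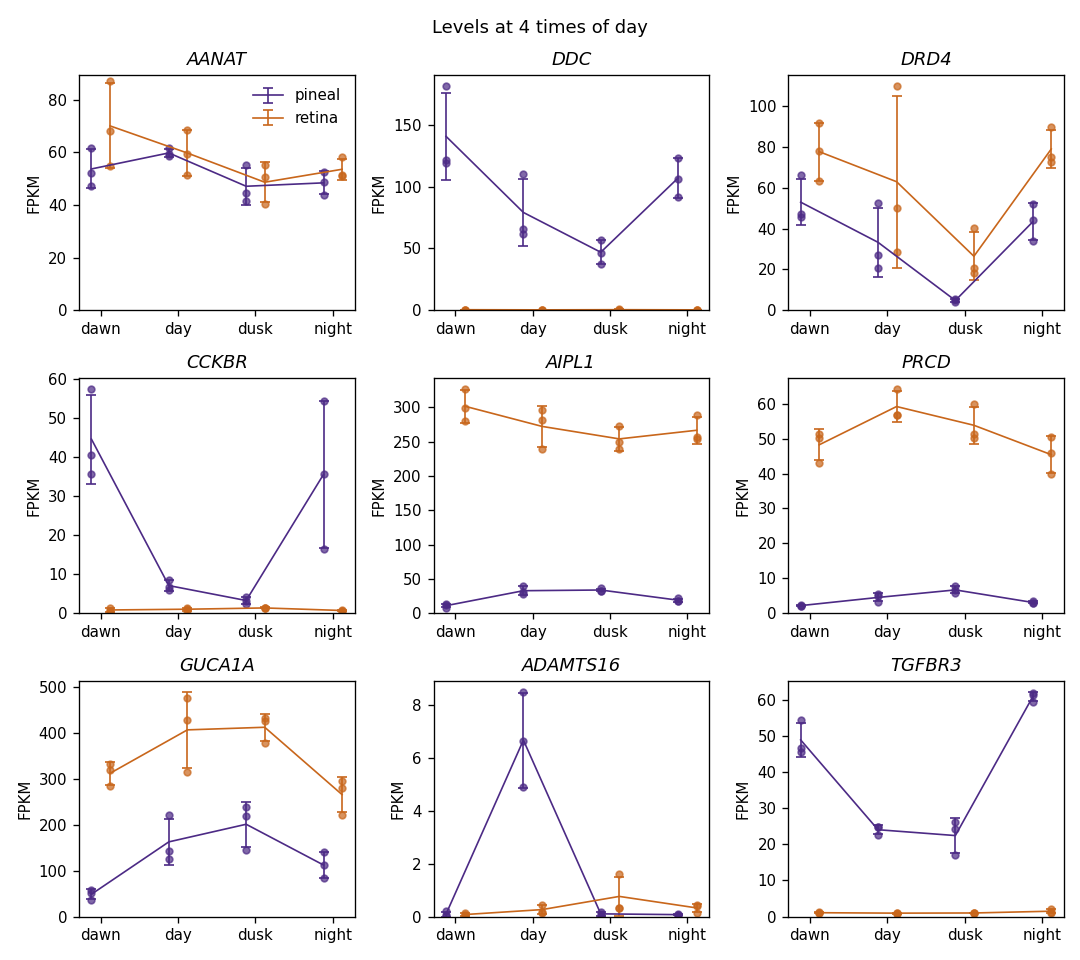
FPKM of named genes at dawn, mid-day, dusk and midnight in the pineal gland and the retina, with points for single libraries and lines with bars for the mean and SD of 3 libraries. In the pineal gland DRD4 goes from 53.0 at dawn to 4.73 at dusk and 43.3 at midnight, while AANAT lies between 47.1 and 59.8 at all 4 times.

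In the retina, 6 of 21890 genes passed the adjusted threshold between dusk and midnight and 0 in the other pairs of times. A count of 0 does not show that no gene differed. XIST was at 39.7 to 49.3 FPKM in the dusk libraries and 0.0219 to 0.0342 in the dawn libraries, yet was not called between dawn and dusk. XIST was high in 3 of 3 dusk and 1 of 3 midnight libraries. With the XIST and EIF1AY indicator in the model limma called 0 of the 6, with 2143 genes at an unadjusted p under 0.05. MYL5, a myosin light chain, was at 1.37 ± 0.481 FPKM at dusk and 7.77 ± 1.17 at midnight (SD, n = 3), a log2 change of 2.16 ± 0.26 (SE, limma adjusted p = 0.0322). MPP4, a scaffold protein of photoreceptor synapses, went from 63.9 ± 7.32 to 116.2 ± 6.65 FPKM (log2 0.86, adjusted p = 0.0322). GALNT10, which starts the O-glycosylation of proteins, went from 13.9 ± 1.28 to 7.49 ± 0.38 (log2 -0.84), and PSRC1, a microtubule protein, from 28.6 ± 1.93 to 15.0 ± 1.59 (log2 -0.91), both with an adjusted p of 0.0322. RP11-399L7.3 (log2 -1.14), named after its values were seen, and a second clone gene (log2 -2.02) were lower. DRD4 was at 77.8 ± 14.2 FPKM at dawn, 63.0 ± 42.2 at mid-day, 26.5 ± 11.9 at dusk and 79.1 ± 9.23 at midnight and did not pass by limma (dusk to midnight log2 1.64, adjusted p = 0.225). In the authors' deposited tables DRD4 passed from dusk to midnight (log2 1.14, DESeq2 adjusted p = 5.62e-07). There it also passed from dawn to dusk (-0.93, DESeq2 adjusted p = 0.000111), but not from mid-day to dusk (-0.34, DESeq2 adjusted p = 0.999). Between mid-day and midnight, AANAT was at 59.7 ± 8.68 and 53.6 ± 3.94 FPKM (log2 -0.15, adjusted p = 0.742), ASMT at 1.84 ± 2.31 and 5.75 ± 2.41 (log2 1.79, adjusted p = 0.362) and DUSP1, an immediate early phosphatase, at 45.8 ± 16.6 and 19.4 ± 1.60 (log2 -1.16, adjusted p = 0.188). The clock genes PER1 (log2 0.36, adjusted p = 0.485), CRY1 (0.51, 0.322) and DBP (0.02, 0.973) did not pass either.

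Heat shock genes had the smallest list p of the retinal time comparisons, between dawn and dusk. XIST was high in 0 of 3 dawn and 3 of 3 dusk libraries, so time and sex went together in these 6. From dawn to dusk HSPA8, a constitutive chaperone, was at 79.1 ± 8.93 and 151.8 ± 3.42 FPKM (SD, n = 3; log2 0.94, limma adjusted p = 0.104) and the mitochondrial chaperone HSPD1 at 21.9 ± 0.859 and 36.2 ± 5.74 (log2 0.70, adjusted p = 0.13). Over all genes 0 of the 11 measured heat shock genes passed, and 8 were higher at dusk adjusted over the list alone (camera adjusted p = 3.65e-10, adjusted p = 0.277 with an estimated correlation). Endoplasmic reticulum stress genes had 0 called over all genes and 6 higher of 13 adjusted over the list alone (8.51e-05; adjusted p = 0.277 with an estimated correlation). From dusk to midnight 9 heat shock genes were lower adjusted over the list alone (1.55e-09; adjusted p = 0.341 with an estimated correlation), and 5 of 23 clock genes were higher (0.00153; adjusted p = 0.455 with an estimated correlation). Rod phototransduction genes had a median log2 change of -0.24 from dawn to dusk, with 0 of 17 called over all genes and 2 lower adjusted over the list alone (1.21e-05; adjusted p = 0.412 with an estimated correlation).

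The counts in the retina depended on which libraries and which tool were used. Limma called 0 genes between mid-day and midnight (2446 at an unadjusted p under 0.05; voom 0 and 2323) and 0 between dawn and mid-day (1707; voom 0 and 1548). It called 0 between mid-day and dusk (800; voom 0 and 820), 0 between midnight and dawn (982; voom 0 and 895) and 0 between dawn and dusk (2336; voom 0 and 2177). At an unadjusted p under 0.05, 1094.5 genes were due by chance in each limma test, more than the 800 and the 982. In the F test limma called 0 (2234) and voom 4 (2028). Without the libraries with many genes at 0, dawn 2 and mid-day 1, limma called 1 gene in each of these except dawn to dusk, where it called 2, and 9 from dusk to midnight, 5 of which were among the 6. From dusk to midnight voom called 6, of which 4 were shared. Leaving out any single midnight library, or dusk 1 or dusk 2, left 0 of the 6 calls, with 1875 to 2018 genes at an unadjusted p under 0.05, and 1 was left without dusk 3. The F test called 2 genes without dawn 1 and 1 without dawn 2, dawn to mid-day and midnight to dawn 1 each without dawn 2, and dawn to dusk 1 without dusk 1 and 1 without dawn 1.

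Whether the times differed in the same way in both tissues was tested directly. The change from mid-day to midnight differed between pineal gland and retina in 7 of 24740 genes. ADAMTS16 (difference of log2 changes -3.74 ± 0.43, SE, limma adjusted p = 0.00158), RFFL (-2.05, adjusted p = 0.00354) and MYL5 (-2.46, adjusted p = 0.00354) had the more negative change in the pineal gland. CTTN, an actin-binding protein (0.70, adjusted p = 0.0209), C9orf142 (1.58, adjusted p = 0.0202) and the clone genes RP11-137H2.6 (1.24) and RP11-488C13.1 (0.87) had the more positive one. The list of adrenergic and cyclic AMP signalling differed between the tissues (median difference 0.31, camera adjusted p = 0.00081, adjusted p = 0.0168 with an estimated correlation), with 0 of 21 genes called over all genes or adjusted over the list alone. Immediate early response (3e-06; adjusted p = 0.467 with an estimated correlation), cytosolic ribosome (9.99e-06; adjusted p = 0.639 with an estimated correlation) and heat shock (0.0109; adjusted p = 0.639 with an estimated correlation) passed with the preset correlation alone. Over the whole 4-time profile, 54 genes differed, among them ADAMTS16 and CCKBR (both adjusted p = 0.000586), AIPL1 (0.00102) and TYRO3 (0.00129), each with a wider range on the log2 scale in the pineal gland. CCKBR in the retina lay between 0.725 and 1.38 FPKM and AIPL1 between 253.9 and 301.6.

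Without the retina libraries dawn 2 and mid-day 1, 5 genes differed in the change from mid-day to midnight, 3 of them among the 7, and 31 in the profile, 19 of them among the 54. voom called 1 and 8 genes. With time and replicate number as a block, all of the 7 calls and most of the 54 were lost. This block joins pineal and retina libraries of equal number, and 6 of these 12 pairs differed in XIST and EIF1AY, so were not from 1 animal. With the XIST and EIF1AY indicator 10 and 33 were called, 6 of them among the 7 and 26 among the 54. The 7 became 147 without pineal mid-day 3, 11 without pineal midnight 2, 3 without retina mid-day 1 and 4 without retina midnight 2. CTTN lost its call without 7 of the 12 libraries (limma adjusted p up to 0.0779), while ADAMTS16, RFFL and MYL5 kept theirs without each. The 54 became 278 without pineal mid-day 3 and 99 without pineal dawn 2. They fell to 34 without pineal midnight 1 or retina midnight 3, 32 without pineal dawn 1, 29 without pineal dusk 1, 26 without pineal midnight 3, 25 without retina mid-day 1, 24 without pineal dusk 2, 20 without retina midnight 1 and 18 without pineal dawn 3. They were 15 without retina dawn 2 or dawn 3, 13 without retina mid-day 2 or dusk 1, 12 without retina dusk 2, dusk 3 or midnight 2, and 11 without retina dawn 1.

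Pineal gland and retina shared part of their photoreceptor and melatonin genes and differed sharply in the rest. TPH1, the first enzyme on the way to serotonin and melatonin, was at 584.2 ± 116.2 FPKM in the pineal gland and 12.7 ± 4.94 in the retina (SD, n = 12; log2 5.52 ± 0.16, limma adjusted p = 4.2e-16), and ASMT at 148.8 ± 31.2 and 3.39 ± 2.68 (log2 5.61). AANAT was at 52.2 ± 7.10 and 58.0 ± 12.0 FPKM and did not pass (log2 -0.14, adjusted p = 0.11). Rod genes were far lower in the pineal gland: PDE6A, the alpha subunit of the rod phosphodiesterase, was at 0.0708 ± 0.0619 FPKM against 337.5 ± 44.1 (log2 -9.21), and SAG, the rod arrestin (log2 -7.97), GNAT1, the rod transducin (-6.49), and NRL, the transcription factor that sets rod fate (-6.91), were lower as well. All 17 rod phototransduction genes were lower (camera adjusted p = 1.5e-09, adjusted p = 0.0175 with an estimated correlation), as were 17 of 18 photoreceptor genes of rods and cones, with 1 higher (1.03e-06; adjusted p = 0.0175 with an estimated correlation). Cone genes were divided, 6 higher and 7 lower of 13 (0.872). Of 11 melatonin synthesis genes 9 were higher and 1 lower (0.000355; adjusted p = 0.0357 with an estimated correlation). Among the largest pineal excesses were LYPD2 (log2 8.13), ETV3L (7.78), CCDC63 (7.71), the choline transporter SLC5A7 (7.44), the serotonin transporter SLC6A4 (7.20) and DDC (6.79). BSX, a homeobox gene, was at 24.9 ± 3.71 FPKM in the pineal gland and listed at 0 in every retina and control library.

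Genes of other cell types also separated the tissues. All 22 called members of the list of other retinal neurons were lower in the pineal gland, of 24 measured (camera adjusted p = 1.7e-06, adjusted p = 0.144 with an estimated correlation), among them GAD2 (log2 -4.31) and VSX1 (-4.35). Higher in the pineal gland were 10 of 10 oligodendrocyte markers (0.000675; adjusted p = 0.308 with an estimated correlation), 7 of 8 astrocyte markers with 1 lower (0.00164; adjusted p = 0.306 with an estimated correlation) and 9 of 9 choroid plexus markers (0.00192; adjusted p = 0.31 with an estimated correlation). So were 10 of 10 markers of microglia and macrophages (2.08e-06; adjusted p = 0.126 with an estimated correlation) and 10 of 11 of connective tissue and vessels with 1 lower (0.000355; adjusted p = 0.221 with an estimated correlation). The astrocyte filament GFAP was at 276.5 ± 80.9 FPKM against 8.37 ± 3.66, and TTR, abundant in choroid plexus, at 580.5 ± 269.7 against 34.1 ± 23.1 (SD, n = 12). Interferon response genes were higher in 15 of 16 (1.78e-06; adjusted p = 0.113 with an estimated correlation), MX1 by log2 2.86. Immediate early genes were higher in 14 of 18 (0.000485; adjusted p = 0.308 with an estimated correlation), MYC by 3.31. Oxidative phosphorylation genes were lower in 27 of 35 and higher in 2 (1.96e-05; adjusted p = 0.308 with an estimated correlation), and ribosomal protein genes lower in 24 of 31 and higher in 3 (0.000355; adjusted p = 0.338 with an estimated correlation). The median over all genes was -0.18.

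The remaining lists were less one-sided. Adrenergic and cyclic AMP genes had 12 higher and 7 lower (camera adjusted p = 0.043, adjusted p = 0.126 with an estimated correlation), with ADRA1B, an alpha-1 adrenergic receptor, at 86.6 ± 14.8 FPKM against 3.93 ± 1.10 (SD, n = 12; log2 4.32). Cholesterol synthesis had 11 higher and 3 lower (0.00797; adjusted p = 0.352 with an estimated correlation) and endoplasmic reticulum stress 9 higher and 2 lower (0.0397; adjusted p = 0.352 with an estimated correlation). Lists that did not pass were core clock, with 6 higher and 12 lower (0.454), pineal and retinal transcription factors, 6 and 8 (0.251), Muller glia, 4 and 6 (0.517), retinal pigment epithelium, 4 and 6 (0.867), tissues of the control pool, 3 and 1 (0.171), heat shock, 4 and 2 (0.334), glucocorticoid response, 7 and 2 (0.0581), retinal dopamine and melatonin signalling, 2 and 6 (0.454), and sex-linked genes, 1 and 1 (0.867). Of the blood list 1 gene, HBB, was measured (log2 0.52, limma adjusted p = 0.29). Adjusted over the list alone, the counts of all 27 lists were the same except for heat shock, with 3 higher and 2 lower.

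In all, 20546 of 24740 genes differed between pineal gland and retina, 8644 higher and 11902 lower in the pineal gland (voom 20403). The share of genes at 0 was lower in 10 of the 12 retina libraries than in every pineal library, so this property of the libraries went together with tissue. Outside the 2 other retina libraries the comparison cannot separate them. The surplus of lower genes was absent against the 2 retina libraries with many genes at 0. Among the 11902, 6944 (58.3%) had clone or noncoding names, and the median log2 difference of such genes was -0.68 against 0.07 for the others. In the dawn and mid-day libraries, where the retina libraries dawn 2 and mid-day 1 were the 2 with as many genes at 0 as the pineal ones, the comparison was repeated with those 2 and without them. With those 2 alone, 8856 genes differed, 4996 higher and 3860 lower, with medians of 0.02 and 0.06, and 8646 of them were among the 20546. Without them, 16173 differed, 6877 higher and 9296 lower, with medians of -0.70 and 0.07. TPH1 (log2 5.74), ASMT (5.92), RPS14 (-1.58) and COX5A (-1.31) kept their calls in the fit on those 2 alone, and 11 named genes did not, among them C1orf51, CLOCK, CSNK1D, DDX3Y, HSPE1, MAT2A, MOBP, NR1D1, PER2 and POMC. The lists were tested again in that fit of 8 libraries, which was chosen after the data were seen. Oxidative phosphorylation had 24 lower and 1 higher of 35 (camera adjusted p = 7.32e-08, adjusted p = 0.421 with an estimated correlation) and the cytosolic ribosome 20 lower of 31 (1.53e-06; adjusted p = 0.412 with an estimated correlation). Adrenergic and cyclic AMP signalling (0.31), cholesterol synthesis (0.425) and endoplasmic reticulum stress (0.229) lost the call, core clock gained it (0.0461; adjusted p = 0.299 with an estimated correlation), and the other called lists kept theirs. Some lists that kept the call had fewer called members: 4 of 10 for oligodendrocytes, 5 of 9 for choroid plexus and 9 of 17 for immediate early response. Microglia and macrophages (10 of 10) and rod phototransduction (16 of 16) had all measured members called. With an estimated correlation 0 of the 26 lists passed in that fit, photoreceptor genes of rods and cones having the smallest adjusted p of 0.0819. Under quantile normalisation 9986 genes were higher and 9984 lower, and the median over all genes was 0.00.

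**Figure D2:**
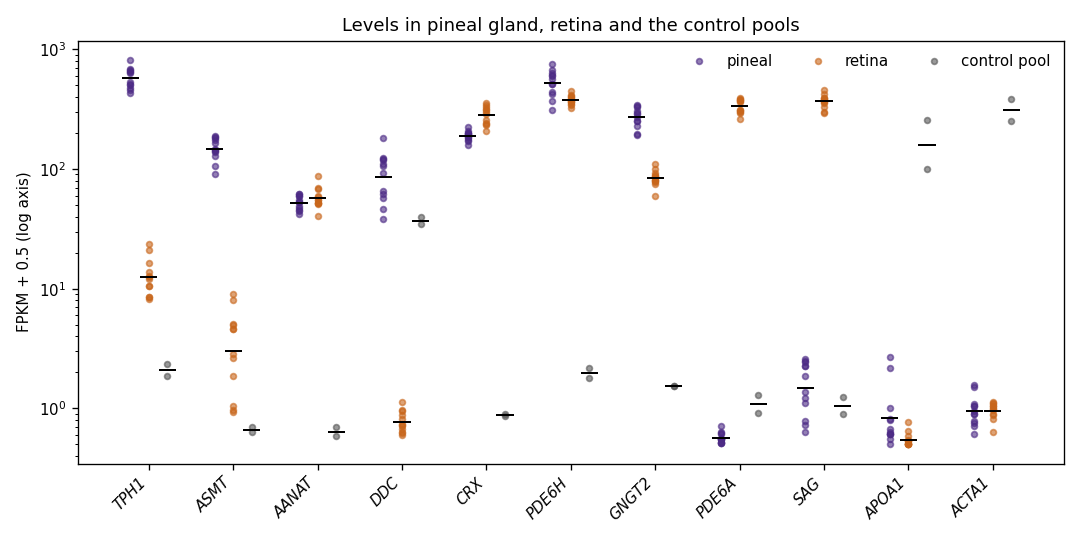
FPKM on a log axis of genes named in the tissue comparisons, with 1 point per library for pineal gland, retina and control pools and black ticks at the geometric mean of FPKM + 0.5. TPH1 averages 584.2 FPKM in the pineal gland and 12.7 in the retina, PDE6A 0.0708 and 337.5, and AANAT 52.2 and 58.0.

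Against the control pools, melatonin enzymes and photoreceptor genes were among the largest excesses of the pineal gland. TPH1 was higher by log2 8.10 ± 0.20 (SE, 12 pineal libraries against 2 pools, limma adjusted p = 7.2e-13), ASMT by 7.78 and AANAT by 6.35, from 0.142 FPKM in the pools to 52.2. The cone genes PDE6H (log2 8.05), GUCA1C (7.90), OPN1SW, the blue cone pigment (7.47), and GNGT2 (7.46), the retinoid-binding protein RBP3 (7.90) and CRX, the homeobox factor of photoreceptors and pinealocytes (7.76), were among the largest excesses. Of the lists, 13 of 16 rod genes were higher (camera adjusted p = 1.97e-06, adjusted p = 0.02 with an estimated correlation) and 8 of 13 cone genes with 1 lower (5.49e-05; adjusted p = 0.00766 with an estimated correlation). So were 13 of 17 photoreceptor genes with 1 lower (3.15e-08; adjusted p = 0.0165 with an estimated correlation) and 9 of 10 transcription factors with 1 lower (1.57e-08; adjusted p = 0.000953 with an estimated correlation). Melatonin synthesis had 7 higher and 2 lower of 11 (0.00446; adjusted p = 0.136 with an estimated correlation). The muscle actin ACTA1 (log2 -8.35) and the liver apolipoprotein APOA1 (-7.59) were far lower, and all 9 measured markers of the control tissues were lower (1.93e-05; adjusted p = 0.0202 with an estimated correlation). Oligodendrocyte markers were lower in 9 of 10 (0.000918; adjusted p = 0.354 with an estimated correlation).

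The lists of photoreceptor genes were higher in the retina than in the control pools. CRX was higher by log2 8.33 (12 retina libraries against 2 pools), the photoreceptor microtubule protein RP1 by 8.43 and AANAT by 6.49, while ASMT was higher by 2.18 (limma adjusted p = 0.028). All 17 rod genes (camera adjusted p = 1.35e-21, adjusted p = 0.0173 with an estimated correlation) and all 18 photoreceptor genes (1.35e-21; adjusted p = 0.00171 with an estimated correlation) were higher. So were 12 of 13 cone genes with 1 lower (8.12e-10; adjusted p = 0.0188 with an estimated correlation) and all 12 measured transcription factors (2.85e-11; adjusted p = 0.000677 with an estimated correlation). Clock genes were higher in 17 of 25 and lower in 5 (0.0118; adjusted p = 0.302 with an estimated correlation), ARNTL by log2 1.59. The cardiac myosin light chain MYL3 was lower (log2 -7.65), and so were 10 of 10 markers of microglia and macrophages (3.79e-08; adjusted p = 0.0478 with an estimated correlation), 5 of 6 of astrocytes (0.000734; adjusted p = 0.0243 with an estimated correlation) and 3 of 3 of oligodendrocytes (0.000671; adjusted p = 0.0173 with an estimated correlation).

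In all, 9696 of 19908 genes differed between pineal gland and pools, 4942 higher and 4754 lower, and 13526 of 22560 between retina and pools, 8320 higher and 5206 lower. The small nuclear RNA 7SK was at 8.88 and 10.4 FPKM in the pools. It was at 1.31 to 2.12 in the retina libraries other than dawn 2 and mid-day 1. The pools had 37.5% and 35.7% of genes at 0, nearer to the 33.5% to 35.2% of those retina libraries. Whether library preparation adds to the difference between retina and pools was not tested. The split of the pineal gland followed the filter and the tool: it was 4951 higher and 11268 lower with no filter, 4213 and 2443 with the filter at FPKM 5, and 4798 and 5547 with voom. For the retina it was 8622 and 12470 with no filter and 5442 and 2648 with the filter at FPKM 5. The split of the retina turned under quantile normalisation, 5665 higher and 6188 lower, and with voom, 4576 and 5843, and the median over all genes went from 0.21 to -0.03 with the former. With 1 pool left out, the remaining pool was assumed to vary like the tissue libraries, and the counts were 6530 without the mid-day pool and 6367 without the midnight pool for the pineal gland, and 8239 and 8100 for the retina. Over the 17378 genes tested in both, 2336 were higher in both tissues than in the pools and 2354 lower in both, where independent calls would give 1342 and 1210. Unchanged groups simulated against the same pools gave 0 in 20 draws. Where no gene is changed hardly any can be called, so these draws do not gauge what the shared pools add. In the data, 590 and 463 genes went in opposite directions. Part of the excess may come from the 2 shared pools, which are too few to be divided.

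The authors' own comparisons were read alongside. In the authors' deposited table for dusk against dawn in the pineal gland 1168 genes had an adjusted p under 0.05, 369 higher and 799 lower, and they included 104 of the 112 genes called here, all 104 in the same direction. In the authors' deposited table for midnight against mid-day in the pineal gland there were 191. The authors' deposited tables for the other pineal pairs had 947 from dusk to midnight, 285 from dawn to mid-day, 261 from midnight to dawn and 23 from mid-day to dusk. In the retina, the authors' deposited tables had 545 genes from dawn to dusk, 508 from dusk to midnight, 327 from mid-day to midnight, 120 from dawn to mid-day, 52 from midnight to dawn and 12 from mid-day to dusk. The authors' deposited table for the retina against control listed 19632, of which 12883 were among the 13526. The authors' deposited table titled for the pineal gland against control held the same values as the retina table in all 50308 entries.

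**Figure D3:**
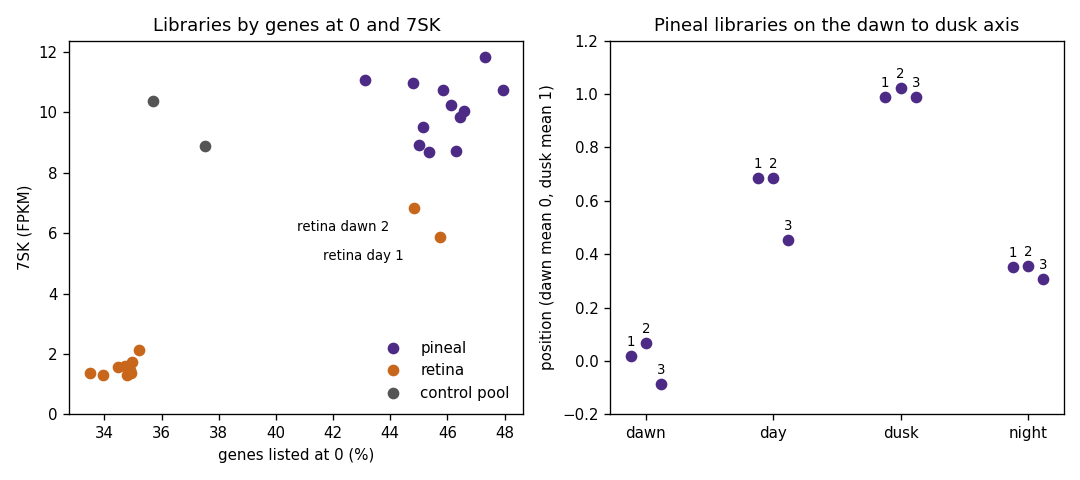
Left, the FPKM of the small nuclear RNA 7SK against the share of genes at 0 in each library, with retina dawn 2 (44.8%) and mid-day 1 (45.7%) apart from the other retina libraries. Right, the place of each pineal library on an axis from the mean of dawn (0) to the mean of dusk (1), on which the places of the dawn and dusk libraries are set by construction and mid-day 3 lies at 0.45 against 0.69 for both other mid-day libraries.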

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

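The tests of reads, TPH1, library preparation, the XIST and EIF1AY indicator, oligodendrocyte markers and a swap were chosen after the result was seen, as were the fits on or without the 2 retina libraries. The splits of the libraries, the thinning of reads and the test for a wrong label were written down before.

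The results below were picked out because the tissues differed in a direct test of that difference. The change from mid-day to midnight differed between pineal gland and retina in 7 genes by limma, with differences of log2 changes of -3.74 for ADAMTS16, -2.46 for MYL5, -2.05 for RFFL, 1.58 for C9orf142, 1.24 for RP11-137H2.6, 0.70 for CTTN and 0.87 for RP11-488C13.1. Among 100 drawn assignments of libraries to times within each tissue, the real one included, 6 gave at least 7 genes and the highest other gave 23, so chance was not excluded for this count. Which libraries the assignment with 23 put together was not examined. The 4-time profile differed in 54 genes, and 1 of 100 assignments, the real one, reached that count, with 25 as the highest other. This argues against chance for the count as a whole, but the assignments were drawn as if no animal gave both tissues. With time and replicate number as a block, all of the 7 calls and most of the 54 were lost. Of the 12 pairs that this block joins, 6 differed in XIST and EIF1AY and were not from 1 animal. The named genes had limma adjusted p-values of 0.000586 for ADAMTS16 and CCKBR, 0.00102 for AIPL1, 0.00129 for TYRO3 and MIR4664, 0.00183 for MYL5, 0.00573 for RFFL, 0.01004 for ACER1, 0.0118 for CADM1, 0.0261 for KCNN1, 0.0407 for XBP1 and 0.0474 for PRCD. With 1 library left out, PRCD lost the call in 20 of 24 fits, XBP1 in 18, KCNN1 in 6 and ACER1 in 1 (adjusted p up to 0.129). Without the 2 retina libraries dawn 2 and mid-day 1 the counts were 5 and 31.

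The first pattern weighed was that retina dawn 2 and mid-day 1 stood apart. They had 44.8% and 45.7% of genes at 0 against 33.5% to 35.2%, and 7SK, an abundant small nuclear RNA, at 6.84 and 5.89 FPKM against 1.31 to 2.12 in the other 10 retina libraries and 8.67 to 11.9 in the pineal libraries. Fewer reads are argued against by a criterion rewritten after its values were seen, since 5 of the other 10 retina libraries held fewer reads than both, and pineal RNA mixed in is argued against, since TPH1 lay above the other 10 in 0 of the 2. A library preparation shared with the pineal libraries may be the source: of 2466 genes at least 4-fold apart between the 2 and 5 of the other libraries, 98.9% had the sign of pineal gland against the remaining 5, where 56.1% were due by the shares of signs. RNA quality was not tested, and no biological explanation was tested.

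The second pattern was the 112 genes called between dusk and dawn in the pineal gland. With the XIST and EIF1AY indicator in the model, their median absolute log2 change kept 99.1% of its size (1.213 to 1.202). Dawn and dusk both held libraries of each side. Genes that followed sex would thus have varied within a time and been less apt to be called. The fitted changes of the called genes were little altered by the indicator, but the way the genes were picked favoured this outcome. It decides little on uneven sex. The calls fell to 31, and the median SE went from 0.198 to 0.204. Why the calls fell was not tested. Of the 60 genes lower at dusk, 3.33% had a within-time correlation above 0.5 with oligodendrocyte markers, against 12% of other genes, but this decides nothing, since genes that varied with carried-over tissue within a time would have been less apt to be called. Brain tissue carried over at dawn therefore stays open. Thinning to 11.7 M reads per library kept 102.05% of the median change of the 112, and 98 genes in all were called in the thinned data. How many of these were among the 112 was not counted, so only the number of calls is known to have stayed near. The kept size of the change decides nothing on depth, since thinning leaves the expected level of each gene as it was. The time of day stays open as the explanation, and so do differences between the animals in age or in date of collection, which were not tested and could each add to these changes.

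The third pattern was pineal mid-day 3, which lay at 0.45 on the axis from dawn to dusk, between the other mid-day libraries (both 0.69) and the midnight libraries (0.31 to 0.35). A swap with a midnight library is argued against, since 0 of the 3 midnight libraries lay nearer to the other mid-day libraries. A wrong label on a midnight library cannot be told apart from a mid-day animal with other levels: over 25 clock genes mid-day 3 was nearer to midnight than to the other mid-day libraries by -0.19 log2 units, which the prediction written beforehand would have read in favour of a wrong label. That reading was withdrawn after the value was seen, because mid-day 1 (-0.06) and mid-day 2 (-0.07) were also nearer to midnight and 4 of 12 libraries were nearest to their own time. ADAMTS16, near 0 at the other times, was expressed in all 3 mid-day libraries, and the library was kept in every result except where stated.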

How the results depend on the processing

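Chosen after the data were seen were voom, its quality weights, the XIST and EIF1AY indicator and the fits that left out, marked or matched the 2 retina libraries dawn 2 and mid-day 1. Where a count below moved, the cause was not tested unless the setting itself gives it.

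With 1 library left out, the counts ran in the pineal gland from 0 to 252 between mid-day and midnight, 0 to 182 from dawn to mid-day, 0 to 4 from mid-day to dusk, 0 to 8 from dusk to midnight, 0 to 1 from midnight to dawn, 0 to 87 between dawn and dusk, 4 to 378 in the F test and 6367 to 6530 against the pools. In the retina they ran from 0 to 0 between mid-day and midnight, 0 to 1 from dawn to mid-day, 0 to 0 from mid-day to dusk, 0 to 1 from dusk to midnight, 0 to 1 from midnight to dawn, 0 to 1 between dawn and dusk, 0 to 2 in the F test and 8100 to 8239 against the pools. The tissue difference ran from 3 to 147 and that of the profile from 11 to 278. Genes seen at mid-day alone fell below the filter when a mid-day library was left out.

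For the pineal gland, the filter at FPKM 5 gave 4 genes between mid-day and midnight, and the 6 mid-day and midnight libraries alone gave 3. voom gave 5 between mid-day and midnight, 3 from dawn to mid-day, 1 from mid-day to dusk and 1 from dusk to midnight. With quality weights it gave 4, 3, 1 and 186 for these, 484 between dawn and dusk and 86 in the F test. The XIST and EIF1AY indicator gave 2 between mid-day and midnight, 2 from dawn to mid-day, 3 from dusk to midnight, 31 between dawn and dusk and 6 in the F test. Replicate number as a block gave 43 in the F test, 21 from dawn to mid-day, 34 from dusk to midnight and 204 between dawn and dusk.

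The block was a planned check of whether equal numbers mark libraries that vary together. Residuals of pineal and retina libraries with the same number had r of -0.06 to 0.17, with 1 of 12 pairs over 0.1 and 8 of 12 best with their own number. Those of pineal times had -0.15 to 0.16, with 6 of 18 over 0.1 and 10 of 18 best with their own number, and those of retina times -0.73 to 0.67, with 1 and 8 of 18. Since not every pair was over 0.1, the numbers were not taken to pair the libraries. XIST and EIF1AY also put 6 of the 12 pineal and retina pairs on different sides.

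For the retina, no filter gave 4 genes between mid-day and midnight and 9 in the F test, and no trend gave 1 in the F test. The block gave 2 in the F test, 1 from dusk to midnight and 1 between dawn and dusk. voom gave 4 in the F test, and with quality weights 32, 128 from dusk to midnight and 233 between dawn and dusk. The XIST and EIF1AY indicator gave 0 from dusk to midnight by limma. Without the 2 retina libraries there was 1 gene in the F test and in each pair that had 0, except 2 between dawn and dusk. Their indicator gave 9 in the F test, 12 from dusk to midnight and 49 between dawn and dusk, and voom without them 8, 34 and 23.

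The tissue difference from mid-day to midnight had 14 genes with no filter, 14 with the filter at FPKM 5, 0 with the block and 1 with voom. The profile difference had 35 with a pseudocount of 0.1, 23 with quantile normalisation, 17 with no trend, 4 with the block, 8 with voom, 33 with the XIST and EIF1AY indicator and 31 without the 2 retina libraries.

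Pineal gland against retina had 12152 with the filter at FPKM 5, which tests fewer genes, 10397 with a 2-fold minimum and 8856 in dawn and mid-day with the 2 retina libraries alone, which uses fewer libraries. Against the pools the pineal gland had 16219 with no filter, which tests more genes, and 4607 with a 2-fold minimum, and the retina 21092, 7675 and, with the filter at FPKM 5, 8090. Of 114 list calls 21 were left with an estimated correlation and 74 with fry. With the pineal and retina lists tested in dawn and mid-day on the 2 retina libraries alone, 112 calls were made, 111 of them shared.

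For single named genes and lists, leaving out 1 library kept 11670 results on their side of the threshold, took the call from 400, added it to 46 and reversed 0. The other settings kept 19349, took it from 435, added it to 142 and reversed 1, HSPE1 between pineal gland and retina under quantile normalisation (log2 0.12, limma adjusted p = 0.553). A change of sign in a gene not called in either setting was counted as kept.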

Other observations

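The splits below were planned, and the tests on retina libraries were chosen after the result was seen.

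With 3 libraries against 3 there were 10 splits, too few for a share under 0.05. In the pineal gland, 1 split reached the real 8 genes between mid-day and midnight (highest other 2), 1 the real 4 from mid-day to dusk (highest other 1), 1 the real 11 from dusk to midnight (highest other 2) and 1 the real 112 between dawn and dusk (highest other 1). From dawn to mid-day 2 splits reached the real 6, the other being mid-day 1, mid-day 3 and dawn 1 against the rest, with 8. From midnight to dawn all 10 reached the real 0 (highest other 1).

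In the retina, 1 split reached the real 6 genes from dusk to midnight (highest other 1). For the pairs with a real count of 0, all 10 did, with a highest other of 1 between mid-day and midnight, 10 from dawn to mid-day, 12 from mid-day to dusk, 1 from midnight to dawn and 0 between dawn and dusk. The split with 10 put mid-day 1, mid-day 2 and dawn 2 together, and so followed the 2 retina libraries that stood apart, and without those 2 the real count was 1. The split with 12 put dusk 1, dusk 2 and mid-day 2 together.

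Over the 4 times in the pineal gland, 2 of 100 drawn assignments, the real one included, reached 20 genes. That share makes chance unlikely for the count but does not exclude it, since the other assignment gave 48. Which libraries it put together was not examined. In the retina all 100 reached the real 0 (highest other 15), which any assignment must, so the test could decide nothing there. Between pineal gland and retina 1 of 100 reached 20546, with 17646 as the highest other, which argues against chance for that count.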
